A study of Mus musculus with 59 samples.

How the data were processed

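Poly(A) RNA of the prefrontal cortex was sequenced from 59 C57BL/6J mice with a stranded mRNA library kit, per the labels' protocols. Samples were grouped by genotype, drug and sex as the labels give them, in 12 groups, 11 of 5 mice and 1 of 4 (WT lithium females).

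The authors quantified transcripts with Salmon 0.11.2 against GRCm38 and normalized gene counts with DESeq2 1.19.11 in R 3.6.0, per the submitters' processing notes. The deposited signal is a normalized count, a gene's count divided by its library's size factor, for 18088 genes in 59 libraries. The notes do not state which genes were left out or whether counts were rounded before scaling. Dividing each library by its smallest step gave whole numbers for 100.0% of the values within 0.001, with a largest deviation of 3.6e-09, so whole reads could be recovered. Totals ran from 22984556 to 35969254 reads per library. Size factors ran from 0.783 to 1.245 and differed from recomputed ones by at most 0.0046 on the log2 scale, and normalized totals ran from 26.2e6 to 30.7e6. Symbols and GRCm38 coordinates from GENCODE were found for 18077 gene IDs; 40 IDs shared a symbol with another and 3 genes were 0 in every library.

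The plan was edgeR for counts and limma for normalized values, and the limma case was used. Values were taken as log2 of the normalized count plus 1. The 16599 genes with a mean normalized count of at least 10 were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend, robust). The model had a mean for each of the 12 groups and 47 residual degrees of freedom, which count pups as independent. All tests were two-sided. Benjamini-Hochberg adjustment was made within each of 15 comparisons at a threshold of 0.05. These were 7 comparisons of arms averaged over the sexes, 2 interactions of genotype with drug, 5 interactions with sex, and females against males in WT vehicle mice. SE values are the moderated standard errors of limma, and SD values are between libraries.

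A set of 36 gene lists was fixed before the data were examined and tested with camera (limma, preset correlation 0.01) and with fry, adjusted over the lists within a comparison, and camera was repeated with a correlation estimated from the data. For every list that camera called, the median, the mean and the test had the same sign. The genes to name were also chosen by a rule written before the data were examined: up to 8 genes per direction by size of change with the same sign in both sexes, up to 4 members of each list that camera called, 10 genes by smallest p where fewer than 8 passed, and up to 5 genes per interaction. The text names a subset of these, and says of any other gene that it was named after its values were seen.

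Correlations of fold changes between comparisons that share vehicle libraries were set beside 100 simulated draws of unchanged groups, and repeated with the vehicle libraries divided by replicate number. Each count of genes was set beside 100 splits of the same libraries, the real one included.

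The steps were tested on simulated counts drawn from the real means, dispersions and size factors of the 16599 genes, with 50 genes changed at each of 4 fold sizes. For HT against WT under vehicle, limma called 19, 37, 47 and 50 of the genes changed 1.2-, 1.5-, 2- and 4-fold, and 7 unchanged genes. In that order, unchanged genes last, lithium in HT mice gave 20, 41, 46, 49 and 9. Genotype by lithium gave 7, 33, 41, 48 and 7. Sex by fluoxetine in WT mice gave 2, 23, 37, 47 and 6. Females against males in WT vehicle mice gave 6, 32, 43, 48 and 7. These draws hold no structure shared between genes, so they do not give error rates for the real libraries.

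Alternatives planned before the data were examined were pseudocounts of 0.5 and 5, quantile normalization, no filter on low values, only the groups compared in the model, the replicate number as a block, 2 surrogate variables (sva 3.50.0), each sex alone, each library left out in turn, and an estimated correlation for the list tests. Others were chosen after seeing the data. These were edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald test) on the recovered reads, the olfactory bulb index as covariates, trends on GC content or transcript length removed within each library (loess, span 0.5, degree 1), both corrections together, and a fit without 6 libraries. Those 6 had an olfactory bulb index over 2.5 or less than 5% mitochondrial reads. The index is the mean over 8 bulb markers, each relative to its mean over all libraries. GC content and length were known for 99.9% of the tested genes. No library was left out of the values reported and 0 columns were unused.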

Results

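Messenger RNA from the prefrontal cortex was sequenced in 59 mice on postnatal day 25. The mice were heterozygous for a Shank3 knock-in allele (HT) or wild type (WT). Shank3 encodes a scaffold protein of the excitatory postsynaptic density. From postnatal day 3 to day 24, a period of 3 weeks, pups received vehicle, fluoxetine or lithium through maternal milk. Fluoxetine is an antidepressant that blocks serotonin reuptake, and lithium is a mood stabilizer that inhibits glycogen synthase kinase 3 and inositol monophosphatase. Genotype, drug and sex formed 12 groups of 5 mice, or 4 in WT lithium females. Group mean reads ran from 26.4e6 in WT fluoxetine females to 34.7e6 in HT lithium males. Of 18088 genes listed, 16599 were tested. Drugs came through the dam, but litters are not labelled, so p-values count pups as independent. Unless a sex is named, each comparison averaged females and males. Changes are log2 fold changes ± SE, adjusted p-values come from limma, and coordinates are GRCm38.

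Lithium had the most genes past an adjusted p of 0.05: 3374 in HT and 2120 in WT mice. With fluoxetine 939 genes passed in WT mice and 46 in HT mice, counts that depended on sex and on single libraries. No gene passed between HT and WT mice under vehicle, fluoxetine or lithium. Among the genes that passed with lithium, 694 were higher and 367 lower in both genotypes, and 4 moved in opposite directions.

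**Figure D1:**
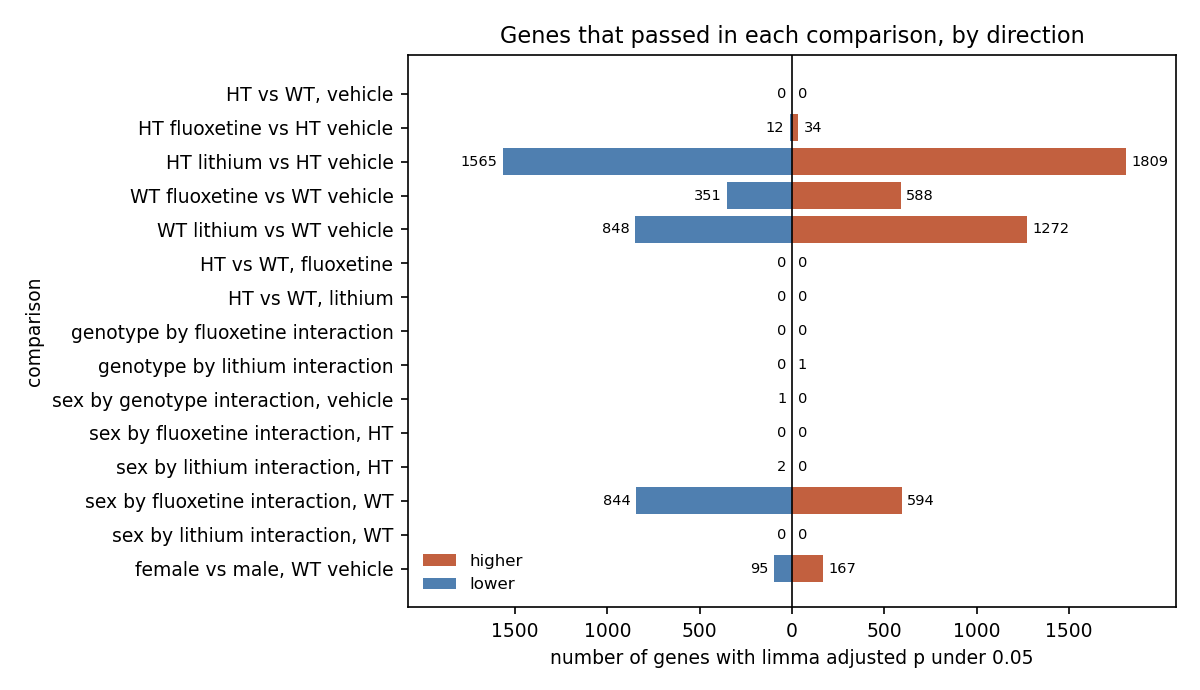
Number of genes with a limma adjusted p under 0.05 (x axis) in each comparison (y axis), with genes that were higher to the right of 0 and genes that were lower to the left. Lithium in HT mice had the longest bars (1809 higher, 1565 lower), and the 3 comparisons of HT with WT mice within a drug had none.

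Shank3 itself (ENSMUSG00000022623, chromosome 15, 89499623 to 89560261) was counted at similar levels in both genotypes without drug. Its mean normalized count was 7351 ± 1000 (SD, n = 10) in HT vehicle mice and 7456 ± 797 (SD, n = 10) in WT vehicle mice, a change of -0.03 ± 0.09 with a limma adjusted p of 0.987. In HT mice lithium raised Shank3 to 9853 ± 1040 (SD, n = 10), a change of 0.43 ± 0.09 with a limma adjusted p of 0.000272 (0.31 in females, 0.55 in males). In WT mice on lithium the mean was 7726 ± 642 (SD, n = 9), and the change of 0.06 ± 0.09 did not pass (limma adjusted p = 0.751). The difference between these lithium effects, 0.37 ± 0.12, did not pass over all genes (limma adjusted p = 0.24), so a genotype-specific effect on Shank3 was not established. Fluoxetine left Shank3 at 7922 ± 750 (SD, n = 10) in HT and 7609 ± 1590 (SD, n = 10) in WT mice, with changes of 0.12 (limma adjusted p = 0.637) and 0.01 (limma adjusted p = 0.979). Counts per gene do not show which allele the reads came from, so these values do not check the genotype labels.

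**Figure D2:**
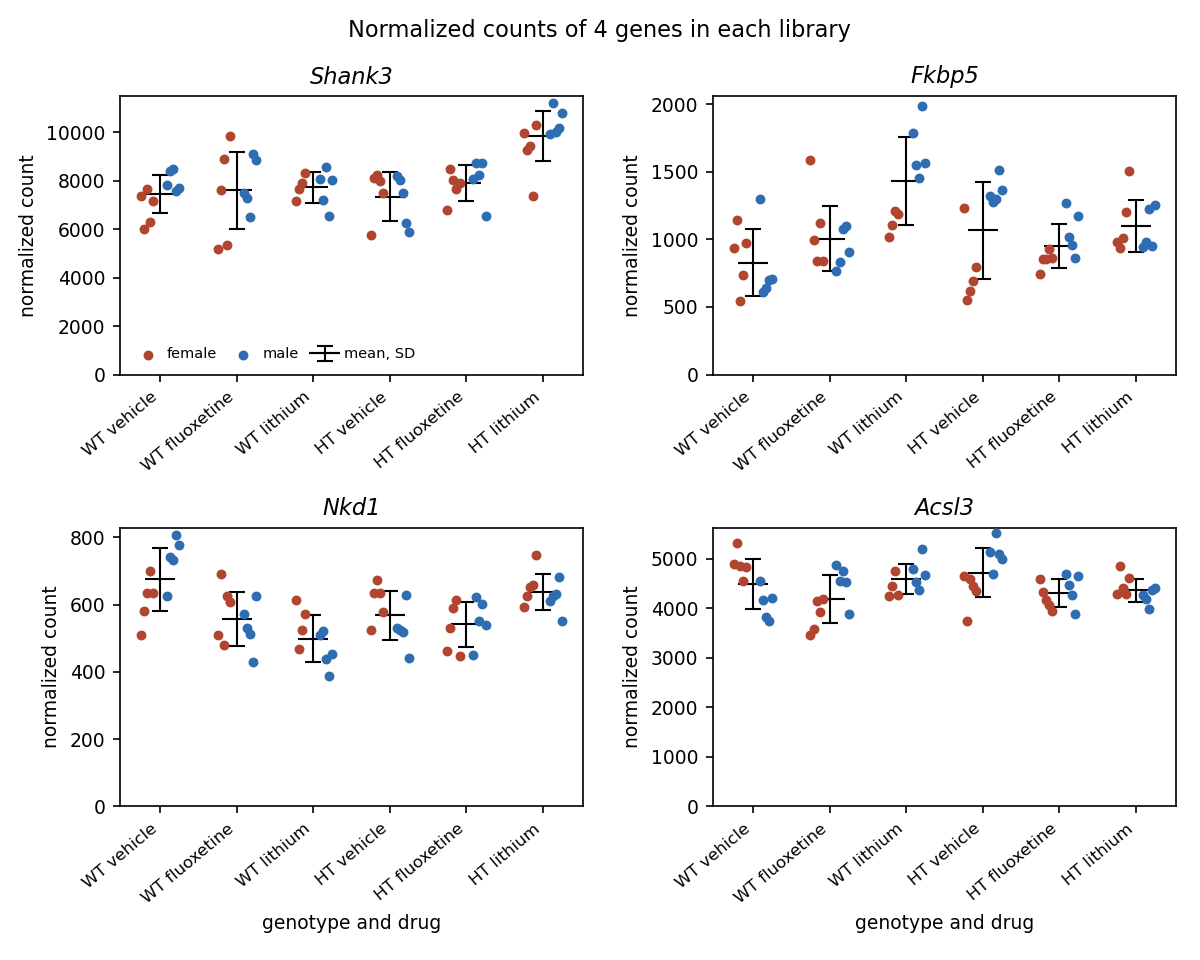
Normalized counts (y axis) of Shank3, Fkbp5, Nkd1 and Acsl3 in each library by genotype and drug (x axis), with a point per library coloured by sex and black lines for the mean and SD of the arm. Shank3 averaged 9853 in HT lithium mice against 7351 in HT vehicle mice.

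HT against WT mice under vehicle asks what the allele does without drug. No single gene passed, and camera called 11 lists, none of which held with an estimated correlation (adjusted p = 0.55 or above). Among them, myelin genes, genes induced by neuronal activity and microglial genes lay lower in HT mice at the median, and genes that respond to glucocorticoids lay higher. The limma test called 0 of 16599 genes, with 1074 at an unadjusted p under 0.05 and a smallest adjusted p of 0.335. DESeq2 called 6 and edgeR 0. Fold changes followed GC content (Spearman -0.42 across genes). Among the 10 genes with the smallest p-values were Txlng (0.28 ± 0.06), Prr5l (-0.62 ± 0.14), Fam118b (0.25 ± 0.06), Pdgfrb (-0.28 ± 0.07) and Sox9 (-0.38 ± 0.10), each with a limma adjusted p of 0.335.

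The 17 markers of myelinating oligodendrocytes, the cells that wrap axons, all lay below 0 in HT mice, at a median of -0.36. None passed over all genes or adjusted over the list alone, camera gave an adjusted p of 3.59e-09, and the value was adjusted p = 0.56 with an estimated correlation. The fatty acid hydroxylase gene Fa2h stood at -0.62 ± 0.23, the transferrin gene Trf at -0.48 ± 0.21, Myrf at -0.45 ± 0.19 and Mbp at -0.42 ± 0.20. Of the 20 activity-induced genes, 15 lay below 0 (median -0.41), among them Fos (-0.70 ± 0.28), Fosb (-0.61 ± 0.24) and Egr4 (-0.45 ± 0.18). Again 0 passed over all genes and 0 adjusted over the list alone; camera gave an adjusted p of 0.000123, against adjusted p = 0.56 with an estimated correlation. The 15 microglia markers had a median of -0.10 and 0 that passed, 1 lower adjusted over the list alone, a camera adjusted p of 0.000502 and adjusted p = 0.56 with an estimated correlation. The 16 glucocorticoid-responsive genes lay higher (median 0.17): 0 passed over all genes, 5 were higher adjusted over the list alone, and camera gave an adjusted p of 0.000502 and adjusted p = 0.55 with an estimated correlation. Members of that list included Sult1a1 (0.50 ± 0.15), Klf9 (0.21 ± 0.07), Map3k6 (0.43 ± 0.14) and Zbtb16 (0.25 ± 0.08). Camera also called lower oligodendrocyte precursor markers (12 genes, median -0.10), Wnt targets (12 genes, -0.09), postsynaptic density proteins (26 genes, -0.06), cholesterol synthesis (23 genes, -0.05) and ribosomal proteins (79 genes, -0.04). It called higher endoplasmic reticulum chaperones (18 genes, 0.06) and choroid plexus and ependymal markers (9 genes, 0.44). None of their members passed over all genes, and 1 Wnt target was lower adjusted over the list alone. Camera adjusted p-values ran from 0.000304 to 0.0121, against adjusted p = 0.55 to 0.89 with an estimated correlation. The choroid plexus gene Ttr stood at 2.13 ± 0.87, with 50300 normalized counts in HT vehicle female 1 and 3.25 to 61.5 in the other libraries of that group. In females alone the activity, microglial, glucocorticoid and ribosomal lists took the opposite sign and the Wnt list the opposite camera direction. Egr4, Sult1a1, Map3k6, Zbtb16 and Klf9 changed sign there too, while the myelin list kept its direction in each sex. Males alone had 106 genes (70 higher, 36 lower) and females 0, and the test of that difference called 1 gene.

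Lithium in HT mice asks what the drug changes in carriers. Of the postsynaptic density genes 16 of 26 rose, among them other members of the Shank family, and of the endoplasmic reticulum chaperones 12 of 18 rose and 1 fell. Of the extracellular matrix genes 7 of 20 rose, of the voltage-gated channels 10 of 32 rose and 1 fell, and no list call of this comparison held with an estimated correlation (adjusted p = 0.58 or above). Effects were small: the median absolute change of the 3374 genes (1809 higher, 1565 lower) was 0.23, and 12 genes exceeded 1.

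Of 26 postsynaptic density proteins, 16 rose, 0 fell and 10 did not pass; 18 rose adjusted over the list alone, camera gave an adjusted p of 4.49e-08, and the value was adjusted p = 0.58 with an estimated correlation. Shank1 (ENSMUSG00000038738, chromosome 7, 44310253 to 44360572) rose by 0.63 ± 0.08 (limma adjusted p = 8.09e-07) and Shank2 (ENSMUSG00000037541, chromosome 7, 144001928 to 144424494) by 0.41 ± 0.07 (limma adjusted p = 1.89e-05). Presynaptic vesicle proteins had 5 of 20 higher, 0 lower and 15 not passed, 6 higher adjusted over the list alone, a camera adjusted p of 0.00558 and adjusted p = 0.73 with an estimated correlation. The active-zone scaffold gene Bsn rose by 0.52 ± 0.09, the vesicle-priming gene Unc13a by 0.34 ± 0.07 and Sv2a by 0.23 ± 0.04. Among 32 voltage-gated ion channels, 10 rose, 1 fell and 21 did not pass (11 and 1 adjusted over the list alone); camera gave an adjusted p of 0.00558 and adjusted p = 0.71 with an estimated correlation. Cacna1a rose by 0.39 ± 0.08, and the fast-spiking potassium channel gene Kcnc1 by 0.23 ± 0.05.

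Of 18 chaperones of the endoplasmic reticulum in the same mice, 12 were higher, 1 lower and 5 not passed, with 14 and 1 adjusted over the list alone. The camera adjusted p was 5.37e-07, against adjusted p = 0.60 with an estimated correlation. Sdf2l1 (ENSMUSG00000022769, chromosome 16, 17130138 to 17132383) rose by 0.65 ± 0.11 (limma adjusted p = 1.32e-05), Pdia4 by 0.35 ± 0.08, Hyou1 by 0.31 ± 0.06 and Calr by 0.28 ± 0.05; Dnajb9, named after its values were seen, fell by 0.23. Of 20 extracellular matrix genes, 7 rose, 0 fell and 13 did not pass, with 8 higher adjusted over the list alone, a camera adjusted p of 0.000528 and adjusted p = 0.58 with an estimated correlation. The neighbouring basement membrane collagen genes Col4a2 (ENSMUSG00000031503, chromosome 8, 11312805 to 11449287) and Col4a1 rose by 0.52 ± 0.06 (limma adjusted p = 3.36e-08) and 0.39 ± 0.06, and the proteoglycan genes Ncan and Bcan by 0.40 ± 0.06 and 0.31 ± 0.07. Among 14 astrocyte markers, 5 rose, 0 fell and 9 did not pass (7 higher adjusted over the list alone), Aldoc by 0.30 ± 0.07 and Fgfr3 by 0.28 ± 0.07; camera gave an adjusted p of 0.00921 and adjusted p = 0.60 with an estimated correlation. Of the 20 activity-induced genes, 4 rose, 0 fell and 16 did not pass, and the same 4 were higher adjusted over the list alone; camera gave an adjusted p of 0.00921 and adjusted p = 0.73 with an estimated correlation. These were Egr2 (0.90 ± 0.33), Egr1 (0.62 ± 0.21), Egr3 (0.33 ± 0.11) and Nptx2 (0.26 ± 0.09). Of 17 myelin markers, 0 were higher, 2 lower (Ugt8a at -0.52 ± 0.18 and Gjc3 at -0.38 ± 0.14) and 15 not passed; 0 passed adjusted over the list alone, camera gave an adjusted p of 0.0184 and adjusted p = 0.73 with an estimated correlation.

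Larger single-gene changes in HT mice on lithium included 2 abundant transcripts. Reads assigned to Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, rose by 0.87 ± 0.17 at a mean normalized count of 8464. Whether reads from similar sequences elsewhere were counted for Lars2 was not tested, so its change is uncertain. The mitochondrial transcript mt-Co2 rose by 0.90 ± 0.28 at a mean of 74130, but it did not pass without HT vehicle female 5 (0.74) or with only the groups compared. Tnfrsf25 rose by 0.98 ± 0.23 and Prr22 by 0.82 ± 0.15, while Gpr149 fell by 1.14 ± 0.28, Slitrk6 by 1.07 ± 0.30 and Mlf1 by 0.92 ± 0.21. Fold changes rose with the GC content of genes (Spearman 0.47 across genes, which are not independent replicates), and with that trend removed 1955 genes passed, 1402 of them among the 3374. Shank3, Shank1, Bsn, Col4a2 and Sdf2l1 kept their call without the trend, whereas Kcnc1 (0.11), Bcan (0.15), Fgfr3, Ugt8a, Gjc3 and the 4 activity-induced genes did not.

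In WT mice, lithium asks for the drug's effect without the knock-in allele. Genes that rose included 7 of 16 glucocorticoid-responsive genes, 10 of 18 endoplasmic reticulum chaperones, 4 of 15 clock genes (1 fell), 8 of 32 ion channels and 12 of 42 autism risk genes (1 fell). Among ribosomal protein genes 18 of 79 fell, and among cholesterol synthesis genes 5 of 23. Camera called these lists, and none held with an estimated correlation (adjusted p = 0.24 or above). In total 1272 genes rose and 848 fell, the median absolute change was 0.23, and 15 genes exceeded 1.

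Of 16 glucocorticoid-responsive genes, 7 rose, 0 fell and 9 did not pass in WT mice on lithium; adjusted over the list alone 9 rose and 1 fell, and camera gave an adjusted p of 4.74e-06 and adjusted p = 0.24 with an estimated correlation. The transcription factor gene Zbtb16 (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222) rose by 0.86 ± 0.09 (limma adjusted p = 1.31e-09), and Map3k6 (ENSMUSG00000028862, chromosome 4, 133240818 to 133252929) rose by 0.71 in females and 1.29 in males (limma adjusted p = 4.9e-06). Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), which encodes a co-chaperone that restrains the glucocorticoid receptor, rose by 0.78 ± 0.13 (limma adjusted p = 5.38e-05), and Tsc22d3 by 0.47 ± 0.08 (limma adjusted p = 0.000121). Sult1a1, named after its values were seen, rose by 0.82 ± 0.15, and the lipid droplet gene Plin4 by 1.18 ± 0.29. Chaperones of the endoplasmic reticulum had 10 of 18 higher, 0 lower and 8 not passed (12 higher adjusted over the list alone), with a camera adjusted p of 1.08e-08 and adjusted p = 0.36 with an estimated correlation. Pdia4 rose by 0.42 ± 0.08, Dnajc3 by 0.33 ± 0.06, Hyou1 by 0.30 ± 0.06 and Herpud1 by 0.27 ± 0.05. In the clock list 4 of 15 genes rose, 1 fell and 10 did not pass, with 7 and 1 adjusted over the list alone, a camera adjusted p of 0.0195 and adjusted p = 0.56 with an estimated correlation. Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324) rose by 0.58 ± 0.09 (limma adjusted p = 1.55e-05) and Arntl by 0.25 ± 0.07, while Dbp, named after its values were seen, fell by 0.32.

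Of 79 cytosolic ribosomal proteins in WT mice on lithium, 0 rose, 18 fell and 61 did not pass, with 23 lower adjusted over the list alone. The camera adjusted p was 1.08e-08, against adjusted p = 0.86 with an estimated correlation. Rps2 fell by 0.29 ± 0.07 and Rpl23 by 0.27 ± 0.06; reads of this family can be shared with near-identical pseudogenes, so single members are uncertain. In cholesterol synthesis 0 of 23 genes rose, 5 fell and 18 did not pass (7 lower adjusted over the list alone), with a camera adjusted p of 0.000269 and adjusted p = 0.86 with an estimated correlation. Insig1, which restrains sterol synthesis, fell by 0.32 ± 0.06, Mvk by 0.28 ± 0.08 and Stard4 by 0.25 ± 0.07. Of 42 autism risk genes, 12 rose, 1 fell and 29 did not pass, with 16 and 1 adjusted over the list alone, a camera adjusted p of 2.65e-05 and adjusted p = 0.36 with an estimated correlation. The chromatin regulator genes Kmt2a and Chd2 rose by 0.33 ± 0.06 and 0.23 ± 0.05, and Tnrc6b by 0.23 ± 0.04. Channel genes had 8 of 32 higher, 0 lower and 24 not passed (10 higher adjusted over the list alone), with Cacna1e at 0.26 ± 0.06; camera gave an adjusted p of 0.000929 and adjusted p = 0.55 with an estimated correlation. Microglia markers had 0 of 15 higher, 2 lower, among them Cx3cr1 at -0.26 ± 0.08, and 13 not passed, 5 lower adjusted over the list alone, a camera adjusted p of 0.0147 and adjusted p = 0.87 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 0 of 75 higher, 5 lower and 70 not passed, with 4 lower adjusted over the list alone, a camera adjusted p of 0.00109 and adjusted p = 1.0 with an estimated correlation.

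Larger single changes in WT mice on lithium included Noxred1 (1.17 ± 0.17), which rose, and Prnd (-1.64 ± 0.44), Aplnr (-1.02 ± 0.27), Myct1 (-0.94 ± 0.20) and Cd180 (-0.82 ± 0.14), which fell. With the olfactory bulb index of the libraries as covariates 3731 genes passed, and with the trend on gene length removed 1264 did. Without the length trend Tnrc6b, Kmt2a, Chd2, Cacna1e and Dbp lost their call, while Zbtb16, Map3k6, Fkbp5, Per2 and Pdia4 kept theirs.

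**Figure D3:**
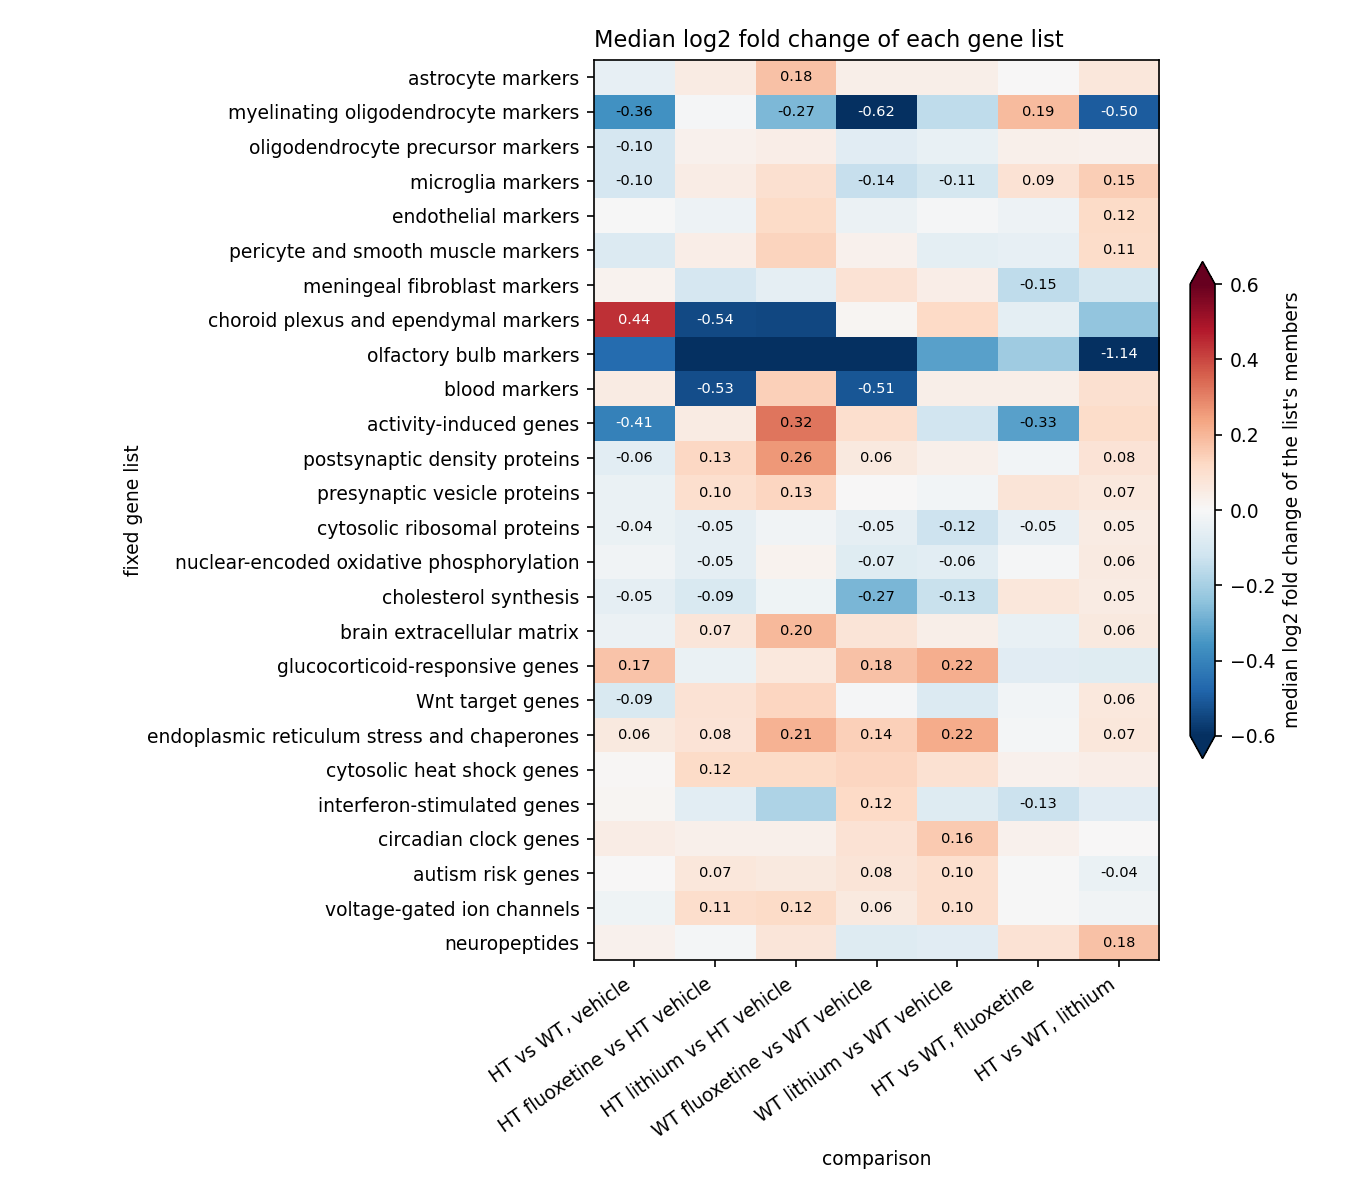
Median log2 fold change of each fixed gene list (y axis) in the 7 comparisons of arms (x axis), as a colour scale that saturates at -0.6 and 0.6, with the value printed where the camera adjusted p was under 0.05. With an estimated correlation none of these 73 calls passed, and a second test, fry, called 8 lists for lithium in HT mice, 6 for lithium and 4 for fluoxetine in WT mice, and 0 in the other 4 comparisons; myelin markers ran from -0.62 in WT mice on fluoxetine to 0.19 between the genotypes on fluoxetine.

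In WT mice on fluoxetine 8 of 17 myelin genes and 12 of 23 cholesterol synthesis genes fell. Upward went 5 of 18 endoplasmic reticulum chaperones, 6 of 42 autism risk genes and 6 of 32 ion channels. Camera called these lists, and none held with an estimated correlation (adjusted p = 0.40 or above). Fold changes rose with transcript length (Spearman 0.26 across genes), and the list tests were not repeated with that trend removed. The 939 genes split into 588 higher and 351 lower, with a median absolute change of 0.22 and 10 genes above 1. Females alone had 2220 genes and males 259.

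Of the 17 myelin markers, 0 rose, 8 fell and 9 did not pass in WT mice on fluoxetine, with 13 lower adjusted over the list alone. The camera adjusted p was 1.56e-09, against adjusted p = 0.54 with an estimated correlation. Opalin fell by 0.79 ± 0.21, Mog by 0.76 ± 0.20 and Ugt8a by 0.69 ± 0.18. In cholesterol synthesis, which supplies myelin with sterol, 0 of 23 genes rose, 12 fell and 11 did not pass, with 16 lower adjusted over the list alone, a camera adjusted p of 1.4e-13 and adjusted p = 0.40 with an estimated correlation. Insig1 (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662) fell by 0.36 ± 0.06 (limma adjusted p = 0.000339), Idi1 by 0.40 ± 0.08, Hmgcs1 by 0.38 ± 0.07 and Sqle by 0.35 ± 0.06. Chaperones had 5 of 18 higher, 0 lower and 13 not passed (9 higher adjusted over the list alone), among them Hspa5 (0.34 ± 0.08), Hyou1 (0.27 ± 0.06) and Calr (0.21 ± 0.05); camera gave an adjusted p of 1.4e-06 and adjusted p = 0.54 with an estimated correlation. Autism risk genes had 6 of 42 higher, 0 lower and 36 not passed, with 12 higher and 1 lower adjusted over the list alone, a camera adjusted p of 3.13e-05 and adjusted p = 0.48 with an estimated correlation. Kmt2a rose by 0.28 ± 0.06 and Tnrc6b by 0.20 ± 0.04. Ion channels had 6 of 32 higher, 0 lower and 26 not passed (7 higher adjusted over the list alone), a camera adjusted p of 0.0043 and adjusted p = 0.62 with an estimated correlation.

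Oxidative phosphorylation genes, 75 of them nuclear-encoded, had 0 higher, 5 lower and 70 not passed (5 lower adjusted over the list alone), with Uqcrc2 at -0.18 ± 0.05 and Atp5f1 at -0.15 ± 0.04; camera gave an adjusted p of 0.00013 and adjusted p = 0.79 with an estimated correlation. The activity-induced genes Egr3 (0.67 ± 0.11) and Nptx2 (0.57 ± 0.09), named after their values were seen, rose with a limma adjusted p of 0.000257 each. They were the only 2 of 20 such genes that passed, 0 fell and 18 did not pass, and camera for that list missed the threshold (adjusted p = 0.058). Camera also called postsynaptic density proteins (5 of 26 higher, 7 adjusted over the list alone), glucocorticoid-responsive genes (1 of 16 higher, 8 over the list alone) and interferon-stimulated genes (0 of 18 passed, median 0.12) as higher. It called microglia markers (1 of 15 lower, 2 over the list alone), blood markers (0 of 5 passed, 5 lower over the list alone) and ribosomal proteins (1 of 79 higher, 1 lower, 0 over the list alone; median -0.05, but 0.04 in females alone) as lower. Camera adjusted p-values for these 6 lists ran from 0.00258 to 0.0376, against adjusted p = 0.54 to 0.85 with an estimated correlation. Low-abundance genes with larger changes were Irs4 (1.12 ± 0.35) and Depp1 (1.09 ± 0.33), which rose, and E2f2 (-0.87 ± 0.18), which fell; Tpm3-rs7 (-1.33 ± 0.25) resembles other tropomyosin genes and is uncertain. The mean olfactory bulb index was higher on fluoxetine than under vehicle in females (2.20) and lower in males (0.54 against 1.13). Without the 6 libraries, 3 of them WT fluoxetine females, 1663 genes passed, 556 of them among the 939. With that index as covariates 1744 genes passed while Ugt8a, Mog and Zbtb16 lost their call, and without the length trend 549 passed while Kmt2a and Tnrc6b lost theirs. Leaving out WT fluoxetine female replicate 2 gave 477 genes and leaving out WT vehicle female replicate 3 gave 575.

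In HT mice 46 genes passed with fluoxetine, 34 higher and 12 lower. Females alone had 111 (62 higher, 49 lower) and males 0; the count was 0 with only the groups compared and 506 with 2 surrogate variables. By camera, synaptic and autism risk genes lay higher and cholesterol synthesis, oxidative phosphorylation and blood genes lower, but no list call held with an estimated correlation (adjusted p = 0.45 or above). Ahdc1 rose by 0.37 ± 0.08 and the neuronal splicing factor gene Nova2 (ENSMUSG00000030411, chromosome 7, 18925888 to 18965319) by 0.35 ± 0.07 (limma adjusted p = 0.0198). The synaptic adhesion gene Nlgn3 (ENSMUSG00000031302, chromosome X, 101299168 to 101325963) rose by 0.27 ± 0.06 (limma adjusted p = 0.0198), Shank1 by 0.35 ± 0.08 and Ncan by 0.29 ± 0.06. The mitochondrial ribosome gene Mrps18c fell by 0.35 ± 0.07, Zfp971 by 0.35 ± 0.08, the sterol enzyme gene Nsdhl by 0.26 ± 0.06 and Selenof by 0.24 ± 0.04. Postsynaptic density proteins had 2 of 26 higher, 0 lower and 24 not passed (5 higher adjusted over the list alone), a camera adjusted p of 6.81e-07 and adjusted p = 0.45 with an estimated correlation. Among 42 autism risk genes, 1 rose, 0 fell and 41 did not pass, with 7 higher adjusted over the list alone, a camera adjusted p of 2.83e-05 and adjusted p = 0.45 with an estimated correlation; Arid1b stood at 0.19 ± 0.05 without passing. Cholesterol synthesis had 0 of 23 higher, 1 lower and 22 not passed (5 lower adjusted over the list alone), a camera adjusted p of 3.27e-05 and adjusted p = 0.58 with an estimated correlation. Of 75 oxidative phosphorylation genes 0 passed, 12 were lower adjusted over the list alone, and camera gave an adjusted p of 1.2e-06 and adjusted p = 0.58 with an estimated correlation. None of the 5 blood markers passed, Hbb-bs stood at -0.65 ± 0.21, all 5 were lower adjusted over the list alone, and camera gave an adjusted p of 6.06e-05 and adjusted p = 0.45 with an estimated correlation; the haemoglobin genes are near-identical copies and uncertain. Camera also called higher presynaptic vesicle proteins (0 of 20 passed, 3 over the list alone), ion channels (0 of 32, 0), chaperones of the endoplasmic reticulum (0 of 18, 4), extracellular matrix genes (1 of 20, 1) and heat shock genes (0 of 11, 2). It called lower ribosomal proteins (0 of 79, 2) and choroid plexus markers (0 of 9, 0; median -0.54), and in males alone the heat shock and ribosomal lists took the opposite camera direction. For these 7 lists camera adjusted p-values ran from 1.78e-05 to 0.0264, against adjusted p = 0.45 to 0.74 with an estimated correlation.

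The count of 46 in HT mice on fluoxetine rested on single libraries. It became 0 without fluoxetine female 5, fluoxetine male 3, vehicle female 3 or vehicle male 5 and 166 without vehicle female 5. Quantile normalization gave 70 genes, edgeR 75 and DESeq2 198.

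The changes under the 2 drugs were set side by side. Across 16599 genes, which are not independent replicates, the fluoxetine and lithium changes correlated at 0.65 in HT and 0.63 in WT mice. Unchanged groups set against the same vehicle libraries gave 0.48 (-0.04 to 0.82) and 0.49 (-0.02 to 0.81) over 100 simulated draws, so both values lay within what shared vehicle libraries give. With separate vehicle libraries for each drug the correlations were 0.30 and 0.20 in HT and 0.27 and 0.33 in WT mice. In WT mice 450 genes were higher and 196 lower under both drugs and 0 passed in opposite directions, and in HT mice 34 and 10 were shared. Shared vehicle libraries raise such overlaps by construction. Lithium changes correlated at 0.43 between HT and WT mice, within the simulated range of -0.51 to 0.55, and 3026 of the 3374 genes of HT mice had the same sign in WT mice. The 694 genes higher and 367 lower in both genotypes, which share no libraries, compare with 139 and 80 for lists of independent genes. The fluoxetine changes of HT and WT mice correlated at 0.35, within the simulated range of -0.63 to 0.54.

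HT and WT mice on lithium were compared to see what genotype changed under the drug. By camera, myelin genes lay lower in HT mice and microglial, endothelial and postsynaptic genes higher, but no list call held with an estimated correlation (adjusted p = 0.57 or above). No gene passed in limma, with 1839 at an unadjusted p under 0.05 and a smallest adjusted p of 0.108. DESeq2 called 37, the fit with 2 surrogate variables 298 and edgeR 0. Fold changes followed GC content (Spearman 0.36 across genes). All 17 myelin markers lay below 0 (median -0.50): 0 passed, 13 were lower adjusted over the list alone, and camera gave an adjusted p of 1.33e-11 and adjusted p = 0.57 with an estimated correlation. Mal stood at -0.70 ± 0.22, Ermn at -0.66 ± 0.21 and Gjc3 at -0.51 ± 0.14. Microglia markers had a median of 0.15 with C1qa at 0.19 ± 0.06 and Tmem119 at 0.26 ± 0.09; 0 of 15 passed, 2 were higher adjusted over the list alone, and camera gave an adjusted p of 0.000116 and adjusted p = 0.57 with an estimated correlation. Endothelial markers, with Kdr at 0.43 ± 0.12 and Tek at 0.34 ± 0.09, had a median of 0.12, 0 of 13 passed and 2 higher adjusted over the list alone; camera gave an adjusted p of 0.0021 and adjusted p = 0.57 with an estimated correlation. Postsynaptic density proteins had a median of 0.08 with Dlgap3 at 0.39 ± 0.12; 0 of 26 passed, 4 were higher adjusted over the list alone, and camera gave an adjusted p of 5.74e-05 and adjusted p = 0.57 with an estimated correlation. The 8 olfactory bulb markers lay lower (median -1.14), with 0 passed over all genes, 0 adjusted over the list alone, a camera adjusted p of 0.00478 and adjusted p = 0.64 with an estimated correlation. In females alone their median was 0.37. Camera also called higher oxidative phosphorylation genes (75, median 0.06), ribosomal proteins (79, 0.05), chaperones of the endoplasmic reticulum (18, 0.07), neuropeptides (15, 0.18; 1 higher over the list alone), and extracellular matrix genes (20, 0.06; 2 higher and 1 lower over the list alone). Higher too were pericyte and smooth muscle markers (10, 0.11), Wnt targets (12, 0.06; 2 higher over the list alone), presynaptic vesicle proteins (20, 0.07; -0.04 in females alone) and cholesterol synthesis (23, 0.05; -0.10 in females alone). It called autism risk genes (42, -0.04) lower, and no member of these 10 lists passed over all genes. Camera adjusted p-values ran from 0.000412 to 0.0391, against adjusted p = 0.57 to 0.71 with an estimated correlation. Without the 6 libraries, 24 genes passed.

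Under fluoxetine, activity-induced genes lay lower in HT than in WT mice at the median, a camera call that did not hold with an estimated correlation (adjusted p = 0.71). No gene passed in limma, with 1883 at an unadjusted p under 0.05 and a smallest adjusted p of 0.123; edgeR called 1, DESeq2 19 and the fit with 2 surrogate variables 212. Egr3 stood at -0.54 ± 0.11, Npas4 at -0.65 ± 0.24, Fosb at -0.73 ± 0.24 and Nptx2 at -0.32 ± 0.09. Of the 20 activity-induced genes 19 lay below 0 (median -0.33), 0 passed, 5 were lower adjusted over the list alone, and camera gave an adjusted p of 6.87e-09 and adjusted p = 0.71 with an estimated correlation. The 15 microglia markers had a median of 0.09; 0 passed, 1 was higher adjusted over the list alone, and camera gave an adjusted p of 0.0227 and adjusted p = 0.92 with an estimated correlation. Camera also called ribosomal proteins (79, median -0.05), interferon-stimulated genes (18, -0.13), meningeal fibroblast markers (13, -0.15) and myelin markers (17, 0.19). None of their members passed over all genes or over the list alone, and camera adjusted p-values were 0.000879 to 0.0227, against adjusted p = 0.92 with an estimated correlation. The olfactory bulb index differed by -0.75 between these arms, and with it as covariates the activity-induced list kept its call and the other 5 lists did not. In males alone the microglia and ribosomal medians were -0.03 and 0.01, and without the 6 libraries the meningeal and ribosomal medians were 0.04 and 0.01. Females alone had 491 genes and males 1, and without WT fluoxetine female 5 the count of 0 became 112; over all single libraries it ran from 0 to 112.

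Genotype by lithium tests whether the drug acts differently in HT and WT mice. A single gene passed: Nkd1 (ENSMUSG00000031661, chromosome 8, 88521354 to 88594884), which encodes a feedback inhibitor of Wnt signalling, the pathway that glycogen synthase kinase 3 restrains. Its interaction was 0.59 ± 0.11 (limma adjusted p = 0.019; 0.28 in females, 0.91 in males). Lithium lowered Nkd1 in WT mice by a change of -0.42 ± 0.08 (limma adjusted p = 0.000162), while the change of 0.17 ± 0.08 in HT mice did not pass (limma adjusted p = 0.0992). Group means in WT mice went from 612 to 544.7 in females and from 737.8 to 462.4 in males, and in HT mice from 608.5 to 655.6 and from 528.6 to 619.7. The count of 1 ran from 0 to 5 over single libraries left out. In 5 of those 39 fits Nkd1 did not pass (adjusted p from 0.0516 to 0.0827). At an unadjusted p under 0.05 there were 2020 genes, and 1090 with the trend on GC content removed (Spearman 0.5 across genes). The fit with 2 surrogate variables called 410, DESeq2 34 and edgeR 2, and females alone had 0 genes and males 335. No sex alone was tested without the GC trend. Fkbp5, named after its values were seen, had an interaction of -0.67 ± 0.18 that did not pass (limma adjusted p = 0.181). Camera called values above 0, a more positive change with lithium in HT mice, for microglia markers (median 0.28; 0 of 15 passed, 8 higher adjusted over the list alone; camera adjusted p = 2.17e-06 and adjusted p = 0.46 with an estimated correlation) and postsynaptic density proteins (median 0.14; 0 of 26 passed, 7 higher adjusted over the list alone; camera adjusted p = 1.29e-05 and adjusted p = 0.47 with an estimated correlation). Glucocorticoid-responsive genes lay below 0 (median -0.19; 0 of 16 passed, 3 lower adjusted over the list alone; camera adjusted p = 0.00148 and adjusted p = 0.47 with an estimated correlation), but in females alone their median was 0.07 and Fkbp5 stood at 0.14.

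For genotype with fluoxetine, limma called 0 genes, with 844 at an unadjusted p under 0.05 and a smallest adjusted p of 0.765; edgeR and DESeq2 called 0 as well, and so did every fit with a single library left out, while males alone had 5. The bulb index differed by -0.75, and with it as covariates 5 of 12 list calls held, that of myelin among them (median 0.47) and that of cholesterol synthesis not (0.02). The myelin list had a median change of -0.62 with fluoxetine in WT mice and of -0.01 in HT mice. All 17 interaction values lay above 0 (median 0.59), with 0 passed over all genes or adjusted over the list alone, a camera adjusted p of 1.78e-11 and adjusted p = 0.46 with an estimated correlation. Cholesterol synthesis genes had a median of 0.12, with 0 of 23 passed over all genes or adjusted over the list alone, a camera adjusted p of 8.88e-06 and adjusted p = 0.74 with an estimated correlation.

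In WT vehicle mice 167 genes were higher and 95 lower in females. Xist, the RNA that silences an X chromosome, had 11400 to 39200 normalized counts in female libraries and at most 10.1 in male libraries. The Y-linked genes Uty (389 to 577), Ddx3y (1180 to 1950), Kdm5d (587 to 1200) and Eif2s3y (538 to 1740) were read in every male library, and no female library exceeded 3.29 for any of them, so all 59 libraries matched their labelled sex. Genes that escape X inactivation were higher in females: Eif2s3x by 0.63 (limma adjusted p = 3.82e-16), 5530601H04Rik by 0.47, Kdm6a and Ddx3x by 0.38 each and Kdm5c by 0.24. The count of 262 became 72, 49, 167 and 137 without WT vehicle females 1, 2, 3 and 4 and 39, 29 and 126 without males 3, 4 and 5. Fold changes followed GC content (Spearman -0.50 across genes), and 27 genes passed with that trend removed.

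Whether drug or genotype effects differ by sex was tested directly. Fluoxetine in WT mice gave 1438 genes (594 with a more positive change in females, 844 with a more negative). Btbd17 (ENSMUSG00000000202, chromosome 11, 114791217 to 114795945) had 1.34 ± 0.22 (limma adjusted p = 0.00175), Nae1 -0.68 ± 0.11, Pcx 0.60 ± 0.11 and Eif1a -0.70 ± 0.13. The changes followed GC content (Spearman 0.50 across genes), the olfactory bulb index differed by 1.64, and 1 gene passed with the GC trend removed and 2 without the 6 libraries. Brain extracellular matrix genes had 5 of 20 more positive, 0 more negative and 15 not passed (5 and 1 adjusted over the list alone), a camera adjusted p of 0.0198 and adjusted p = 0.75 with an estimated correlation. Over single libraries left out the count ran from 557 without fluoxetine male 1 to 2849 without fluoxetine female 5.

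Lithium in HT mice differed by sex in 2 genes of mitochondrial protein import, Timm8b (ENSMUSG00000039016, chromosome 9, 50603910 to 50605320; -0.65 ± 0.12, limma adjusted p = 0.0182) and Tomm5 (ENSMUSG00000078713, chromosome 4, 45105208 to 45108114; -0.64 ± 0.13, limma adjusted p = 0.0436). From vehicle to lithium, Timm8b went from 1784 to 1411 in females and from 1352 to 1650 in males, and Tomm5 from 607.1 to 438.7 and from 458.2 to 509.3. Of 75 nuclear-encoded oxidative phosphorylation genes 73 lay below 0 (median -0.30), 0 passed, 46 were lower adjusted over the list alone, and camera gave an adjusted p of 1.15e-22 and adjusted p = 0.42 with an estimated correlation. Cholesterol synthesis genes lay below 0 in 23 of 23 cases (median -0.36), with 0 passed, 13 lower adjusted over the list alone, a camera adjusted p of 3.71e-10 and adjusted p = 0.42 with an estimated correlation. The 8 olfactory bulb markers lay above 0 at the median (3.62; 0 passed, 5 higher adjusted over the list alone; camera adjusted p = 8.11e-05 and adjusted p = 0.42 with an estimated correlation). With a single library left out, Timm8b did not pass in 8 of 20 fits and Tomm5 in 14 (adjusted p up to 0.222). At an unadjusted p under 0.05 there were 2838 genes, and DESeq2 called 138. The count of 2 ran from 0 to 93 over single libraries left out. It was 0 with bulb covariates, with Timm8b at -0.57 and Tomm5 at -0.58 (median SE from 0.122 to 0.125). It was 0 too without the length trend, where their median absolute change fell from 0.645 to 0.382 (median SE 0.092).

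The allele's effect without drug differed by sex in 1 gene, the acyl-CoA synthetase gene Acsl3 (ENSMUSG00000032883, chromosome 1, 78657825 to 78707743), at -0.48 ± 0.09 (limma adjusted p = 0.0465). Its means were 4357 in HT and 4891 in WT females, and 5089 in HT and 4101 in WT males; the count was 491 with 2 surrogate variables and ran from 0 to 21 over single libraries left out, and in 13 of those 20 fits Acsl3 did not pass (adjusted p up to 0.231). Among lists, camera called activity-induced genes above 0 (median 1.03; 0 of 20 passed, 10 higher adjusted over the list alone; camera adjusted p = 1.13e-05 and adjusted p = 0.40 with an estimated correlation), and glucocorticoid-responsive genes below 0 (median -0.35; 0 of 16 passed, 6 lower adjusted over the list alone; camera adjusted p = 1.02e-05 and adjusted p = 0.13 with an estimated correlation). Fluoxetine in HT mice gave 0 genes by sex in limma, with 881 at an unadjusted p under 0.05, 0 in edgeR and 5 in DESeq2, and 0 to 5 over single libraries left out. Lithium in WT mice gave 0 in limma, with 1467 at an unadjusted p under 0.05, 0 in edgeR, 28 in DESeq2 and 157 with 2 surrogate variables, and 0 to 8 over single libraries left out. Camera called activity-induced genes below 0 in the sex by fluoxetine test of HT mice (median -0.71; 0 of 20 passed, 5 lower adjusted over the list alone; camera adjusted p = 1.38e-10 and adjusted p = 0.22 with an estimated correlation), and pericyte and smooth muscle markers above 0 in the sex by lithium test of WT mice (median 0.33; 0 of 10 passed, 2 higher adjusted over the list alone; camera adjusted p = 5.07e-05 and adjusted p = 0.18 with an estimated correlation).

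Libraries also differed in olfactory bulb markers. An index of 8 bulb markers ran from 0.062 to 4.27, a 69.4-fold range, and tracked the first principal component, which held 21.3% of the variance (absolute Pearson 0.97). By group it averaged 2.20 ± 2.03 (SD, n = 5) in WT fluoxetine females and 0.13 ± 0.07 (SD, n = 5) in HT lithium males.

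**Figure D4:**
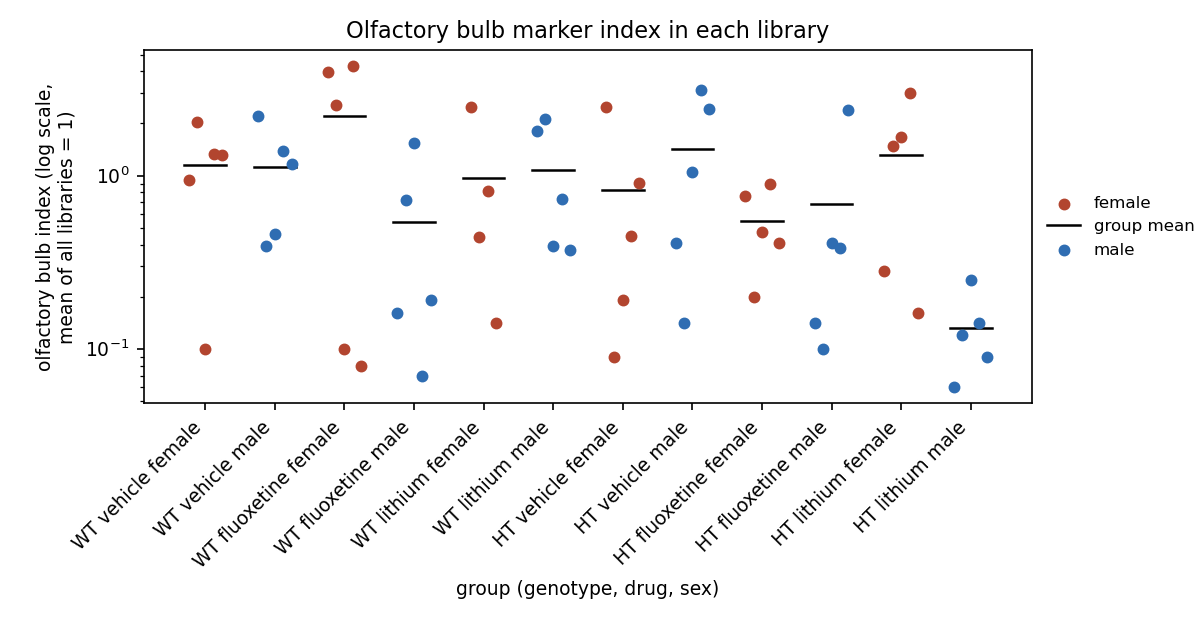
Olfactory bulb index (y axis, log scale, mean of all libraries = 1) of each library by group (x axis), with a point per library coloured by sex and a bar at the group mean. Values ran from 0.062 to 4.27.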

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

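Tests of explanations, counts over splits and measures of single libraries were chosen after the results were seen. The interaction tests and gene lists were planned.

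In WT mice the fluoxetine effect differed between females and males for 1438 genes. Of 100 splits of the libraries, the real split included, 4 gave as many, a share too near 0.05 for 100 splits to exclude chance. The highest of the others, 3255, points to a structure of the samples. A gene length trend is argued against as the whole cause, with 1559 genes with it removed (1331 shared), and with olfactory bulb content as covariates 1355 genes passed, 838 of them among the 1438 (median absolute log2 fold change from 0.456 with a median SE of 0.125 to 0.373 with 0.116). Bulb content, the libraries in doubt and a drug effect cannot be told apart, because 2 genes passed without the 6 libraries in doubt (0.311 with 0.134), 3 of these being WT fluoxetine females with an index of 2.56 to 4.27, which left 2 libraries of that group. A GC content trend between libraries may account for the difference, since the GC slope was 0.097 in WT fluoxetine females and -0.043 in males against -0.066 and 0.064 under vehicle, and with the trend removed 1 gene passed because the folds shrank (0.264 with 0.113; 1437 of the 1438 had the same sign), and 0 passed with both corrections. A response to fluoxetine that differs by sex stays open as untested, because a real response that followed GC content would be removed along with the trend.

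Lithium moved 3374 genes in HT and 2120 in WT mice. Of 100 splits only the real one gave as many in each genotype (highest of the others 609 and 1444). Chance can be excluded for each taken alone, but 100 splits cannot exclude it over all comparisons. A litter effect cannot be excluded by splitting single pups. Olfactory bulb tissue content is argued against as the whole cause, with 4474 genes in HT and 3731 in WT mice with it as covariates (3234 and 2120 shared), and so are the libraries in doubt, with 2742 genes in HT mice without them (2391 shared). A gene length trend is argued against as the whole cause in HT mice (3327 genes with it removed, 2918 shared), and a GC content trend in WT mice (2602, 2080 shared). Other calls ended because folds shrank: without the GC trend 1955 genes passed in HT mice, 1402 of them among the 3374 (median absolute change from 0.234 with a median SE of 0.062 to 0.152 with 0.056, 3352 with the same sign), and without the length trend 1264 passed in WT mice, 1056 of them among the 2120 (0.231 with 0.061 to 0.18 with 0.059, 2115 with the same sign). For these ended calls, a GC trend in HT mice or a length trend in WT mice and a lithium response that follows GC content or length cannot be told apart, because changes followed GC in HT mice (Spearman 0.47; slopes of 0.058 and 0.07 in lithium females and males, -0.046 and -0.089 under vehicle) and length in WT mice (0.34), and the correction removes either.

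Olfactory bulb markers differed between libraries, and HT fluoxetine male 5 lay far from the other 4 samples of its group, with an index of 2.4 against 0.0974 to 0.405. A cause that acts through genotype, drug or sex alone is argued against, because 5 other bulb genes tracked the index within the groups at r = 0.97. A candidate source is olfactory bulb tissue in some samples: those 5 genes, chosen from bulb markers outside the fixed list, tracked the index over 59 libraries at r = 0.97 (0.97 without the 2 farthest libraries, permutation p = 1e-05, the smallest that 100000 resamples can give). From the library with the lowest index to the one with the highest, Cdhr1 went from 72.8 to 6510, Doc2g from 107 to 4580 and Th from 35.6 to 1950, and 5 of the 8 markers exceeded 10 normalized counts in all 59 libraries. Regulation of these genes within the cortex was not tested and stays open.

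Of 156 tests of 13 measures in 12 groups, 16 found a sample far from the others of its group. Chance gives about 1 in 20 groups, but Ttr, Pagr1a and Rsc1a1, with most of the 16, were chosen after the results were seen. No excess was established. In units of 1e6 reads, HT fluoxetine female 5 had 35.9 (others 26.2 to 28.3) and HT lithium female 4 had 23 (others 29.8 to 30.7). The mitochondrial share of WT vehicle male 5 was 7.53% (others 6.59% to 6.79%). Fkbp5 had 1300 normalized counts in WT vehicle male 1 (others 613 to 705). Ttr, which is abundant in choroid plexus, had 50300 in HT vehicle female 1 (others 3.25 to 61.5), 202 in HT vehicle male 2 (2.55 to 7.49), 6 in WT fluoxetine male 3 (2.12 to 3.01) and 11 in WT vehicle female 1 (2.75 to 3.46). Pagr1a had 374 in HT lithium female 3 (others 19.8 to 69.9), 64.5 in HT vehicle female 3 (6.5 to 15.5), 383 in WT lithium female 2 (18.6 to 24.4) and 239 in WT vehicle male 3 (25.1 to 62.7). Rsc1a1 had 10.2 in HT lithium male 4 (others 52.1 to 66), 135 in HT vehicle female 5 (8.38 to 41.2) and 124 in WT lithium male 4 (53.9 to 69.2).

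Group differences were also called for single genes. Nkd1 had a genotype by lithium interaction of 0.59, and 7 of 100 splits gave as many genes as the 1 called (highest of the others 829), so chance cannot be excluded. Acsl3 had a sex by genotype interaction of -0.48, where 8 of 100 splits gave as many as 1 gene (highest of the others 968), so chance cannot be excluded. Timm8b and Tomm5 had sex by lithium interactions of -0.65 and -0.64 in HT mice, where 5 of 100 splits gave as many as 2 genes (highest of the others 1155), so chance cannot be excluded. Splits far above the real 1 or 2 genes point to a structure of the samples other than the groups.

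Camera called 12 gene lists for genotype by fluoxetine, 14 for genotype by lithium, 11 for sex by genotype, 13 and 6 for sex by fluoxetine in HT and WT mice, and 12 and 14 for sex by lithium in HT and WT mice. With an estimated correlation, the list of Y-linked and X-inactivation genes in the sex by genotype test passed and no other of these lists did. All 5 members lay below 0 (median -0.77), 0 passed over all genes, 2 were lower adjusted over the list alone, and camera gave an adjusted p of 0.000738 and adjusted p = 0.039 with an estimated correlation; most of these genes are read in a single sex, so their values in the other sex rest on few reads.

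Among the other comparisons, 1 of 100 splits gave as many as the 262 genes of females against males (highest of the others 43). For the 46 genes of fluoxetine in HT mice 2 of 100 did (highest 293). Chance can be excluded for the 262 taken alone but not over 15 comparisons. It cannot be for the 46, which became 0 when any of 4 single libraries was left out and with only the groups compared. Nor can it for the 939 genes of fluoxetine in WT mice, where 5 of 100 splits gave as many (highest 3268). Where limma called 0 genes the count of splits, 100 of 100, was fixed beforehand and decides nothing; the highest of the others was 8 for HT against WT mice under vehicle, 285 under fluoxetine, 3 under lithium, 3 for genotype by fluoxetine, 35 for sex by fluoxetine in HT mice and 322 for sex by lithium in WT mice. Splits far above the real count (293 against 46, 3268 against 939) point to a structure of the samples.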

How the results depend on the processing

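Tests with edgeR and DESeq2, bulb covariates, GC and length corrections and the fit without 6 libraries were chosen after the results were seen. The rest were planned. Depth ran from group means of 26.4e6 to 34.7e6 reads and limits the genes of low abundance: 16599 of 18088 genes were tested. Among 231 changes of named genes, direction and side of the threshold were kept by 231 and 230 with pseudocounts of 0.5 and 5, 226 without the filter, 224 with the replicate number as a block, 220 with quantile normalization, 221 with edgeR and 209 with DESeq2. The numbers were 201 with only the groups compared, 200 with 2 surrogate variables, 213 with bulb covariates, 198 with the GC trend removed, 200 with the length trend removed, 197 with the GC correction and bulb covariates together and 205 without the 6 libraries. Of 214 changes tested in each sex, 142 were kept in females and 124 in males, and over single libraries left out 4246 of 4554 were kept. Of 104 list results, 98 were kept with the GC trend removed, 83 with bulb covariates, 88 without the 6 libraries, 101 with the block, 103 without the filter and 8 with an estimated correlation. Fewer libraries enter the fits of only the groups compared and without the 6 libraries, while each sex is a contrast within the full fit. Other causes of the differences were not tested.

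Over single libraries left out, limma called 0 to 2 genes for HT against WT mice under vehicle, 0 to 112 under fluoxetine and 0 to 2 under lithium. Fluoxetine gave 0 to 166 in HT and 477 to 1311 in WT mice, and lithium 2782 to 3578 and 1562 to 2273. Genotype by fluoxetine gave 0 to 0, genotype by lithium 0 to 5, sex by genotype 0 to 21, sex by fluoxetine 0 to 5 in HT and 557 to 2849 in WT mice, sex by lithium 0 to 93 in HT and 0 to 8 in WT mice, and females against males 29 to 380. Shank3 ran from -0.052 to 0.021 for HT against WT mice under vehicle and from -0.051 to 0.065 for fluoxetine in WT mice, and Inpp1 from -0.013 to 0.03 for lithium in WT mice.

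Quantile normalization gave 70 genes for fluoxetine in HT mice, 1 for HT against WT mice under fluoxetine, 3 for genotype by lithium and 0 for sex by genotype, and Shank3 reversed to -0.021 for fluoxetine in WT mice. No filter on low values gave 0 for sex by genotype. Only the groups compared in the model gave 0 genes for fluoxetine in HT mice, 424 for fluoxetine in WT mice, 3 for HT against WT mice under lithium, 435 for sex by fluoxetine in WT mice, and 0 and 1 for sex by lithium in HT and WT mice. The replicate number as a block gave 0 for sex by genotype and 48 for females against males, and Inpp1 reversed to -0.001 for lithium in WT mice. Replicate numbers do not pair the samples, since libraries of the same number and sex correlated at -0.044 to 0.062 on average after group means were removed.

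The fit with 2 surrogate variables gave 506 and 3172 genes for fluoxetine in HT and WT mice, 5146 and 4381 for lithium, 212 and 298 for HT against WT mice under fluoxetine and lithium, 410 for genotype by lithium and 491 for sex by genotype. It gave 1 and 2680 for sex by fluoxetine in HT and WT mice, 0 and 157 for sex by lithium, and 1973 for females against males. With edgeR there were 75 genes for fluoxetine in HT mice, 1 for HT against WT mice under fluoxetine, 2 for genotype by lithium, 0 for sex by genotype and 1 for sex by lithium in HT mice. DESeq2 called 6, 19 and 37 for HT against WT mice under vehicle, fluoxetine and lithium, 198 for fluoxetine in HT mice, 34 for genotype by lithium, 12 for sex by genotype, 5 for sex by fluoxetine in HT mice, 138 and 28 for sex by lithium in HT and WT mice, and 582 for females against males.

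In females alone fluoxetine gave 111 and 2220 genes in HT and WT mice, lithium 1924 and 1196, HT against WT mice under fluoxetine 491 and genotype by lithium 0. For HT against WT mice under vehicle, values that reversed in females were Shank3 0.117, Egr4 0.095, Sult1a1 -0.05, Klf9 -0.032, Map3k6 -0.244, Zbtb16 -0.045, Cx3cr1 0.017, Dnajc3 -0.007, Rps20 0.018 and Sox9 0.017, and list medians were 0.031 for microglia markers, 0.088 for activity-induced genes, 0.018 for ribosomal proteins, -0.047 for glucocorticoid-responsive genes and -0.006 for Wnt targets, whose camera direction reversed. Others that reversed in females were Cdhr1 0.293 for HT against WT mice under lithium, Fkbp5 0.14 for genotype by lithium and Impa1 -0.04 for lithium in WT mice. List medians were 0.036 for ribosomal proteins with fluoxetine and -0.058 for serotonin system genes with lithium in WT mice, 0.369 for bulb markers, -0.038 for presynaptic proteins and -0.097 for cholesterol synthesis between the genotypes under lithium, and 0.067 for glucocorticoid-responsive genes in genotype by lithium.

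In males alone HT against WT mice gave 106, 1 and 1 genes under vehicle, fluoxetine and lithium, fluoxetine 0 and 259 in HT and WT mice, lithium 1608 and 437, genotype by fluoxetine 5 and genotype by lithium 335. Reversed values in males were Fkbp5 -0.348 for lithium in HT mice and Shank3 -0.039 and -0.061 for fluoxetine and lithium in WT mice. Among lists, medians were 0.009 for ribosomal proteins and 0.017 for heat shock genes, whose camera direction reversed, with fluoxetine in HT mice, and -0.026 for microglia markers and 0.01 for ribosomal proteins between the genotypes under fluoxetine.

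Olfactory bulb content as covariates gave 134 and 1744 genes for fluoxetine in HT and WT mice, 3731 for lithium in WT mice, 3 for HT against WT mice under lithium, 31 for genotype by lithium, 3 for sex by genotype, 0 and 21 for sex by lithium in HT and WT mice and 1035 for females against males; Shank3 reversed to -0.039 between the genotypes under fluoxetine. Removing the GC trend gave 1955 genes for lithium in HT mice, 2 for genotype by lithium, 1 and 1 for sex by fluoxetine in HT and WT mice, 24 and 1 for sex by lithium and 27 for females against males, and Shank3 reversed to 0.06 for HT against WT mice under vehicle and -0.021 for fluoxetine in WT mice. Removing the length trend gave 15 and 549 genes for fluoxetine in HT and WT mice, 1264 for lithium in WT mice, 2 for genotype by lithium and 0 for sex by lithium in HT mice, with Shank3 at -0.049 for fluoxetine and -0.033 for lithium and Inpp1 at -0.048 for lithium in WT mice.

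The GC correction together with bulb covariates gave 131 and 2213 genes for fluoxetine in HT and WT mice, 4399 for lithium in WT mice, 2 for HT against WT mice under lithium, 5 for genotype by lithium, 5 for sex by genotype, 1 and 0 for sex by fluoxetine in HT and WT mice, 0 and 10 for sex by lithium and 146 for females against males. Shank3 reversed there to 0.066 for HT against WT mice under vehicle and -0.025 for fluoxetine in HT mice. Without the 6 libraries there were 92 and 1663 genes for fluoxetine in HT and WT mice, 3 and 24 for HT against WT mice under fluoxetine and lithium, 2 for genotype by lithium, 2 for sex by genotype, 0 for sex by lithium in HT mice, 2 for sex by fluoxetine in WT mice and 551 for females against males. Shank3 was -0.114 between the genotypes under fluoxetine, where list medians were 0.043 for meningeal fibroblast markers and 0.013 for ribosomal proteins, and the ribosomal median was 0.033 in the sex by fluoxetine test of WT mice, where the camera direction reversed.

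With an estimated correlation, 0 of the 73 list calls between arms passed. Fry called 0 lists for genotype by fluoxetine and 1 for genotype by lithium, 2 for sex by genotype, 0 and 3 for sex by fluoxetine in HT and WT mice and 2 and 2 for sex by lithium. With vehicle replicates 1, 3 and 5 in the first and 2 and 4 in the second comparison, the correlation with the genotype effect reversed from -0.39 to 0.14 for fluoxetine and from -0.31 to 0.20 for lithium in HT mice, and fluoxetine against lithium gave 0.30 in HT and 0.27 in WT mice. With the other division these were -0.03, -0.15, 0.20 and 0.33. Comparisons that share vehicle libraries are correlated by construction: simulated draws gave -0.47 for each drug against the genotype effect.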

Other observations

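Tests and lists here were planned, and the genes named here were chosen after their values were seen.

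Lithium inhibits inositol monophosphatase, but camera called inositol genes in neither genotype. Of 16599 genes, 2120 passed in WT and 3374 in HT mice. In WT mice on lithium 3 of 16 inositol phosphate and phosphoinositide genes rose, 0 fell and 13 did not pass (3 higher adjusted over the list alone), with a camera adjusted p of 0.0531 and adjusted p = 0.55 with an estimated correlation. Slc5a3 (ENSMUSG00000089774, chromosome 16, 92058322 to 92087473), which encodes an inositol importer, rose by 0.49 ± 0.09 (limma adjusted p = 7.09e-05), and the inositol synthesis gene Isyna1 by 0.27 ± 0.08 (limma adjusted p = 0.0213). In HT mice on lithium 3 of these 16 genes rose, 2 fell and 11 did not pass (3 and 2 adjusted over the list alone), with a camera adjusted p of 0.275 and adjusted p = 0.73 with an estimated correlation. Isyna1 rose by 0.26 ± 0.08 (limma adjusted p = 0.0134) and Pi4ka by 0.22 (limma adjusted p = 0.0045), whereas Slc5a3 at 0.19 ± 0.08 did not pass (limma adjusted p = 0.0888). Impa1, which encodes inositol monophosphatase 1, fell by 0.12 ± 0.04 in HT mice (limma adjusted p = 0.049) and stood at 0.10 ± 0.05 in WT mice without passing (limma adjusted p = 0.132). The interactions with genotype, -0.30 ± 0.12 for Slc5a3 (limma adjusted p = 0.301) and -0.22 ± 0.06 for Impa1 (limma adjusted p = 0.197), did not pass, so no difference between genotypes was established. Inpp1 fell by 0.13 in HT mice (limma adjusted p = 0.0475) and stood at 0.01 in WT mice (limma adjusted p = 0.925).

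Among 15 serotonin system genes, 0 rose and 1 fell with lithium in HT mice (0 and 1 adjusted over the list alone; camera adjusted p = 0.309 and adjusted p = 0.73 with an estimated correlation), and 0 rose and 1 fell in WT mice (2 and 1 adjusted over the list alone; camera adjusted p = 0.937 and adjusted p = 1.0 with an estimated correlation). The gene was Maoa, which encodes the monoamine oxidase that degrades serotonin: it fell by 0.21 ± 0.05 in HT and 0.17 ± 0.05 in WT mice on lithium, and by 0.20 ± 0.05 in WT mice on fluoxetine (limma adjusted p = 0.00275, 0.0262 and 0.0162). Of 15 clock genes, 5 rose, 2 fell and 8 did not pass in HT mice on lithium (6 and 2 adjusted over the list alone), with a camera adjusted p of 0.156 and adjusted p = 0.73 with an estimated correlation; Per2 rose by 0.50 ± 0.09, Per1 by 0.48 ± 0.11 and Cry2 by 0.25. Of 15 microglia markers, 4 rose, 0 fell and 11 did not pass in the same mice (5 higher adjusted over the list alone; camera adjusted p = 0.0871 and adjusted p = 0.73 with an estimated correlation), among them Csf1r (0.35 ± 0.08), Tmem119 (0.31) and C1qa (0.22). The 5 genes that escape X inactivation had 1 higher, 3 lower and 1 not passed in HT mice on lithium (1 and 4 adjusted over the list alone; camera adjusted p = 0.0685 and adjusted p = 0.71 with an estimated correlation), with Kdm5c at 0.21 and Kdm6a, Eif2s3x and Ddx3x at -0.22, -0.17 and -0.17.

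The glucocorticoid-responsive genes Zbtb16 and Map3k6 rose in HT mice on lithium by 0.55 ± 0.08 (limma adjusted p = 5.89e-06) and 0.55 ± 0.14 (limma adjusted p = 0.00365), while Fkbp5 at 0.11 ± 0.13 did not pass (limma adjusted p = 0.588). Xist passed with lithium in WT mice at 1.02 (limma adjusted p = 0.0203), with 0.20 in females and 1.83 in males, where WT lithium males had 2 to 11 reads and WT vehicle males 0 to 7. Pagr1a rose by 2.05 in HT mice and Rsc1a1 by 2.27 in WT mice on lithium, and both genes had samples far from the others of their groups.

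The fluoxetine and lithium changes of HT mice correlated with the genotype difference under vehicle at -0.39 and -0.31 across 16599 genes, which are not independent replicates. Unchanged groups that share those vehicle libraries gave -0.47 for both on average over 100 simulated draws, and the covariances were -0.00989 and -0.0109 against simulated -0.012 and -0.0119. These values therefore give no evidence that either drug moved the HT profile toward that of WT mice.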
